A study of Mus musculus with 6 samples.

How the data were processed

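Total RNA of mouse liver was labelled with biotin and hybridized to Affymetrix arrays, per the labels' protocols. The deposited values are linear intensities per probe set, all positive and with 2 decimals, for 45101 probe sets on 6 arrays. How the authors summarized probes, corrected background and scaled the arrays before depositing these intensities is not given in the sources used here, and the genome build is not given either, so no coordinates are printed. Arrays were grouped by the genotype and numbered by the replicate number in their labels, 3 Mig-6 f/f and 3 Mig-6 d/d.

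Probe sets were named through the platform's annotation, in which 34945 had 1 gene symbol, 932 had several and 9160 had none, besides 64 control probe sets. The Entrez number of 34741 of those with 1 symbol was found in the reference gene table (assembly GRCm38.p6, used for names and for which genes neighbour each other), and 0 symbols needed an update. Probe sets with several symbols or none, and control probe sets, stayed out of the gene tests. The highest probe set by mean stood for each gene, and probe sets in the lowest 40% by mean were left out, at a log2 value of 6.01 or an intensity of 48.4, which left 13718 genes.

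Intensities were used as log2(intensity + 16). The medians and the lower and upper quartiles of the arrays differed by up to 0.185, 0.143 and 0.160 log2. As this exceeded the tolerance of 0.1 log2 set beforehand, arrays were quantile normalized. The genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Prior and residual degrees of freedom were 4.18 and 4. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were joined with pandas 2.3.3.

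A total of 37 gene lists, 3 of them on cholesterol synthesis, bile acid synthesis and sterol transport, was fixed before the data were examined. Of their 657 distinct genes, 577 had a named probe set, and the rest were not analysed here. Each list was tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry, adjusted by Benjamini-Hochberg over the 37 lists. The lists share members, so their results are not independent. The design, the alternatives and the rule for named genes were also fixed before the data were examined. The rule names Errfi1, up to 12 genes in each direction that passed with separate groups, 18 key genes, up to 4 members past the threshold from each list, and the most abundant member of a passing list of another cell type. Other genes are said to have been picked after their values were seen. RNA integrity was compared as the 3-prime minus 5-prime difference of the control probe sets for Actb and Gapdh, with an exact permutation test over 20 assignments, and its alternatives were chosen after seeing the data.

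The gene test was checked on 10 simulated data sets of the 13718 genes with the residual spread of these arrays and 200 genes changed. It called 32.0% of genes changed 1.5-fold, 76.2% of those changed 2-fold, 97.0% at 4-fold and 99.0% at 8-fold, with 8.4 false among 160.5 calls on average, and made 0 calls when no gene was changed. These shares hold for 200 changed genes. The arrays themselves gave 13 calls, and with fewer calls the adjustment asks for a smaller p. The shares called here are therefore lower than those simulated. Alternatives covered the scaling between arrays, the dim filter, the probe set per gene, the variance model, array weights, the replicate number as a block, each array left out, pseudocounts of 1 and 64, all probe sets, and another threshold. Outliers within groups were not tested, as this needs at least 4 samples.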

Results

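Livers of male mice aged 8 weeks, taken after a fast of 24 h, were profiled on 6 Affymetrix mouse expression arrays. The labels give 3 arrays the genotype Mig-6 f/f and 3 the genotype Mig-6 d/d, on a mixed background. Mig-6 is the protein of Errfi1, a feedback inhibitor of the epidermal growth factor receptor family. The series names cholesterol homeostasis and bile acid synthesis as its subject. The comparison asks which liver transcripts differ between the genotypes, and sterol and bile acid genes were tested as groups. The labels do not say whether each array holds a separate animal, so p-values measure the spread between these samples. Median deposited intensities lay between 55.6 and 65.4, and the number of arrays limits the precision. Differences are d/d minus f/f on the log2(intensity + 16) scale with the standard error of limma, n = 3 per group, and they understate the change of dim genes.

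Errfi1 fell in the d/d livers by 68.5 times on the scale with 16 added. It went from a deposited intensity of 5494 ± 169 to 63.2 ± 4.37 (SD, n = 3), a log2 difference of -6.10 ± 0.10 (limma with Benjamini-Hochberg adjustment, adjusted p = 5.07e-08). The f/f arrays read 5371, 5424 and 5686, and the d/d arrays 68.0, 61.8 and 59.6, near the intensity of 48.4 under which probe sets were left out as dim. The other probe set of Errfi1 went from 2898 ± 78.7 to 59.1 ± 3.45 (SD, n = 3). Which part of the gene was deleted, and where the probe sets lie relative to it, is not given in the sources used here. Egfr, the receptor that Mig-6 binds, had a log2 difference of -0.071 ± 0.20 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.945, 95% interval -0.52 to 0.38). Its probe sets ranged from -0.82 to -0.0039. The sign of the one used turned without f/f replicate 3 (0.15) or d/d replicate 3 (0.038), and leaving out 1 array gave -0.21 without f/f replicate 1 to 0.15 without f/f replicate 3. The list of receptor family members, ligands and ERK response genes had a mean of 0.053 and a median of -0.028 over 28 members. Of these, 0 passed in limma and 6 had an unadjusted p under 0.05 (list test by camera with Benjamini-Hochberg adjustment, adjusted p = 0.775), and the mean ran from -0.00093 without d/d replicate 3 to 0.12 without d/d replicate 1.

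Besides Errfi1, 6 genes fell and 6 rose in the d/d livers. The falls were Igfbp1, a secreted binding protein of insulin-like growth factors (4.37 times lower), Mfsd2a, a lysophospholipid transporter (3.53 times), Slc25a25, a mitochondrial ATP carrier (2.87 times), G6pc, the catalytic subunit of glucose-6-phosphatase (2.37 times), Csad, an enzyme of taurine synthesis (2.21 times), and Cyp8b1, which sets the share of cholic acid among bile acids (2.03 times). The rises were Lpl, lipoprotein lipase (4.19 times higher), Cib3, a calcium-binding protein (3.7 times), Rgs16, a regulator of G protein signalling (3.24 times), Abcd2, a peroxisomal fatty acid transporter (2.91 times), Plxna2, a semaphorin receptor (1.98 times), and Hgfac, the activator of hepatocyte growth factor (1.87 times). Igfbp1 went from 4318 ± 930 to 953 ± 68.6 in deposited intensity and Lpl from 228 ± 61.8 to 981 ± 177 (SD, n = 3).

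**Figure D1:**
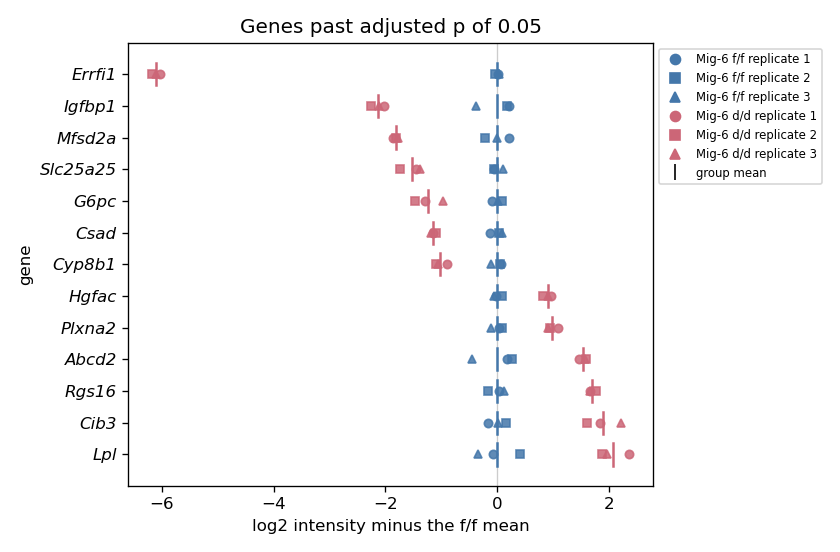
Each point is one array's log2 intensity minus the mean of the f/f arrays (x axis, log2 units), for the 13 genes past the threshold (y axis). Blue points are Mig-6 f/f, red points Mig-6 d/d, shapes mark replicate numbers and vertical strokes the group means; the 3 arrays of each group lie apart from the other group for all 13 genes, from -6.10 for Errfi1 to 2.07 for Lpl.

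The log2 differences were -2.13 ± 0.17 for Igfbp1, -1.82 ± 0.13 for Mfsd2a, -1.52 ± 0.13 for Slc25a25, -1.25 ± 0.14 for G6pc, -1.14 ± 0.11 for Csad and -1.02 ± 0.11 for Cyp8b1. They were 2.07 ± 0.21 for Lpl, 1.89 ± 0.17 for Cib3, 1.70 ± 0.11 for Rgs16, 1.54 ± 0.19 for Abcd2, 0.98 ± 0.11 for Plxna2 and 0.90 ± 0.10 for Hgfac. Of 13718 genes tested, these 13 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, with adjusted p from 5.07e-08 for Errfi1 to 0.0315 for Abcd2, and 1076 genes had an unadjusted p under 0.05 where 685.9 would be reached with no effect. Groups did not overlap for 2013 genes, 14.7%. Over the 10 splits of the 6 arrays into 3 and 3 this share averages 10%, which is not a bound for 1 split. Single splits varied widely: at an unadjusted p under 0.05 in limma, splits that mixed the genotypes had 123 to 1742 genes. The lowest sizes among other probe sets were 0.59 for Rgs16, 0.14 for Abcd2, 0.35 for Plxna2 and -0.21 for Slc25a25, those of Abcd2 and Plxna2 on probe sets under the dim filter. Averaging all probe sets of a gene ended the calls of Plxna2 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0608) and Slc25a25 (adjusted p = 0.0534), at 0.67 and -0.78, where adjusted p over all alternatives ran from 0.0015 to 0.195 and from 0.00028 to 0.0537. Abcd2 had 1.01 with this average and passed. A pseudocount of 1 ended the calls of Abcd2 and Hgfac (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0582 and 0.0508), and a common median that of Hgfac (adjusted p = 0.0598). With the replicate number as a block, Errfi1 alone passed. The other called genes then had adjusted p from 0.0537, for Igfbp1, Mfsd2a, Rgs16 and Slc25a25, to 0.192 for Hgfac (limma with Benjamini-Hochberg adjustment). Errfi1, Igfbp1, Mfsd2a and Rgs16 passed in each of the 6 fits that left out 1 array. Without f/f replicate 1, 2 or 3, 7, 9 and 13 of the 13 genes passed, among 7, 14 and 82 in all, and without d/d replicate 1, 2 or 3, 4, 6 and 7 passed, with no others. Slc25a25 and Cib3 did not pass without d/d replicate 1 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0524 and 0.076), and Csad did not pass without any one d/d array (adjusted p from 0.0807 to 0.1). Lpl and Abcd2 did not pass without f/f replicate 1 or any one d/d array (adjusted p from 0.0807 to 0.1 and from 0.0832 to 0.23). Plxna2 and Hgfac passed in this series of fits only without f/f replicate 3 (adjusted p in the others from 0.0725 to 0.195 and from 0.0744 to 0.218, limma with Benjamini-Hochberg adjustment).

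The array of f/f replicate 3 stood apart from the other 5. Its 18S ribosomal RNA control probe sets averaged 3807, 8.36 times the highest other array at 455.2, and its mean correlation with the other arrays was 0.952 where theirs were 0.974 to 0.978. The first principal component, 51.7% of the variance, separated it from the rest. The difference between the 3-prime and 5-prime control probe sets, a measure of RNA integrity, was 1.26 ± 0.10 (log2, SD) for Actb in f/f and 1.26 ± 0.04 in d/d (n = 3 each, two-sided exact permutation p = 1). For Gapdh it was 0.28 ± 0.04 and 0.32 ± 0.05 (SD, n = 3 each, two-sided exact permutation p = 0.5), where 0.1 is the smallest p that 3 against 3 allows.

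**Figure D2:**
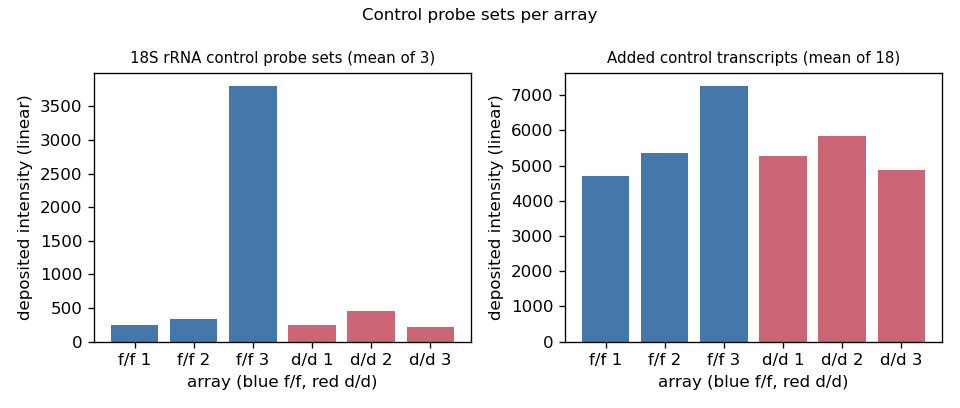
Bars give the mean deposited intensity (linear scale, from 0) of the 3 probe sets for 18S ribosomal RNA (left) and of the 18 probe sets for control transcripts added before hybridization (right), one bar per array, f/f blue and d/d red. The bar of f/f replicate 3 is the highest in both panels, at 3807 and 7266.

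Among bile acid genes, Cyp8b1 fell from 5397 ± 270 to 2596 ± 196 in deposited intensity (SD, n = 3), a log2 difference of -1.02 ± 0.11 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0211). Cyp7a1, the rate-limiting enzyme of the classical pathway, had -1.01 ± 0.22 (adjusted p = 0.197, limma with Benjamini-Hochberg adjustment), with deposited intensities of 1181 ± 289 and 575 ± 154 (SD, n = 3), and did not pass. It passed with array weights, which gave f/f replicate 3 a weight of 0.178 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0228, and from 0.0228 to 0.664 over its alternatives). Cyp7b1 and Cyp27a1, enzymes of the alternative pathway, had -0.85 ± 0.21 and -0.37 ± 0.097 (adjusted p = 0.274 and 0.299, limma with Benjamini-Hochberg adjustment). Of the 16 members tested, 1 fell and 15 did not pass over all genes. Adjusted over the list alone, Cyp8b1, Cyp7a1, Cyp7b1 and Cyp27a1 passed as lower and Cyp2c70, which makes muricholic acids and was picked as an example after its values were seen, as higher, with a log2 difference of 0.51 ± 0.14. The list as a whole had a mean of -0.13 and a camera adjusted p of 0.249 with Benjamini-Hochberg adjustment. In the mixed test of fry, where members may move either way, it passed (Benjamini-Hochberg adjusted p = 0.000155), as 1 of 16 lists that did. The call of Cyp8b1 ended without f/f replicate 1 or 2 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0832 and 0.078) and without d/d replicate 1, 2 or 3 (adjusted p = 0.105, 0.176 and 0.138), with log2 differences between -1.08 and -0.98.

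Genes of cholesterol synthesis lay lower in the d/d livers as a group: 18 of the 20 members tested had a negative difference, with a mean of -0.57 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.86e-09). The call was lost with the correlation between members taken from the data (adjusted p = 0.334 with an estimated correlation). Over all genes 0 of the 20 passed in limma, 11 had an unadjusted p under 0.05, and 8 passed as lower when adjusted over the list alone. Of the key genes fixed beforehand, Insig1, a sensor of sterols, had -1.03 ± 0.35, Sqle, squalene epoxidase, -0.57 ± 0.33 and Srebf2, the transcription factor of the pathway, -0.096 ± 0.13 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.488, 0.758 and 0.891). Srebf2 had -0.016 without f/f replicate 2, -0.20 without f/f replicate 3, -0.052 without d/d replicate 1 and -0.15 without d/d replicate 3, -0.21 with array weights and -0.18 averaged over its probe sets. Members picked after their values were seen were Fdps (-1.61 ± 0.31), Msmo1 (-1.28 ± 0.31), Idi1 (-1.25 ± 0.34) and Hmgcs1 (-0.97 ± 0.24). Averaged over all probe sets of a gene, Fdps had -0.89, Msmo1 -0.51 and Hsd17b7, at -0.87 ± 0.15 otherwise, -0.52. Among f/f arrays, replicate 2 read highest for 18 of the 20 members, and without it the mean was -0.34 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000264, and adjusted p = 0.443 with an estimated correlation). Sqle had -0.15 without f/f replicate 2 and -0.88 without f/f replicate 3. The mean without f/f replicate 3 was -0.74, with 5 members past the threshold as lower, Fdps, Idi1, Hmgcs1, Hsd17b7 and Tm7sf2. Markers of Kupffer cells, the macrophages of the liver, lay lower as well, with 13 of 15 lower and a mean of -0.22 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00126, and adjusted p = 0.334 with an estimated correlation).

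**Figure D3:**
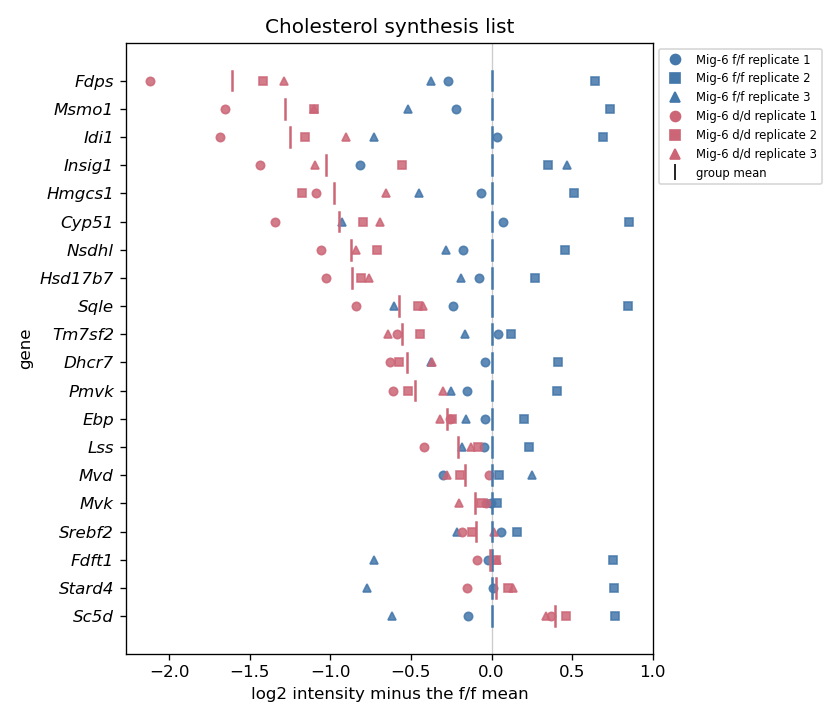
Each point is one array's log2 intensity minus the mean of the f/f arrays (x axis, log2 units) for the 20 members tested of the cholesterol synthesis list (y axis), with f/f blue, d/d red, shapes for replicate numbers and strokes for group means. Group differences run from -1.61 for Fdps to 0.39 for Sc5d, and f/f replicate 2 lies to the right of the other f/f arrays for 18 members.

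Of 20 transporters of sterols and bile acids tested, 0 passed over all genes, 2 had an unadjusted p under 0.05, and Abca1 and Atp8b1 passed as higher when adjusted over the list alone. Abca1, which exports cholesterol to lipoproteins, had a log2 difference of 0.62 ± 0.11 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.123), and its other probe sets 0.22 and 0.29. Averaged over its probe sets it had 0.38. It passed with array weights (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0194, and from 0.0194 to 0.598 over its alternatives). Abcg5 and Abcg8, the biliary sterol exporter, had -0.074 ± 0.099 and 0.0087 ± 0.10, and the bile acid carriers Slc10a1 and Abcb11 0.055 ± 0.099 and -0.015 ± 0.10. Their 95% intervals were -0.30 to 0.15, -0.22 to 0.24, -0.17 to 0.28 and -0.24 to 0.21. The signs of Abcg8, Slc10a1 and Abcb11 turned under some settings, Slc10a1 with the values as deposited (-0.00237), Abcg8 without f/f replicate 3 (-0.027) or d/d replicate 2 (-0.022) and Abcb11 without d/d replicate 2 (0.024). With 1 array left out, Abcg8 ran from -0.027 without f/f replicate 3 to 0.036 without d/d replicate 3, Slc10a1 from 0.026 without d/d replicate 2 to 0.085 without f/f replicate 3 and Abcb11 from -0.052 without d/d replicate 1 to 0.024 without d/d replicate 2. The transport list had a mean of -0.0073 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.904), and this mean ran from -0.025 without d/d replicate 1 to 0.019 without d/d replicate 3. The bile acid receptor Nr1h4 had 0.11 ± 0.10 (0.066 without f/f replicate 3) and its target Nr0b2 -0.29 ± 0.24. Nr0b2 had -0.069 without f/f replicate 1, -0.068 without d/d replicate 2 and -0.44 without d/d replicate 1. Their list of nuclear receptors and coregulators had a mean of 0.037 over 18 members (camera with Benjamini-Hochberg adjustment, adjusted p = 0.398), which ran from -0.014 without f/f replicate 3 to 0.081 without f/f replicate 1 with 1 array left out.

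In the fasting list, Igfbp1 and G6pc fell and the other 14 of 16 members did not pass, with a mean of -0.30 and 12 members lower (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000538, and adjusted p = 0.173 with an estimated correlation). The call of G6pc ended without f/f replicate 1 or 2 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0832 and 0.101) and without d/d replicate 1 or 2 (adjusted p = 0.195 and 0.176). Pck1, which like G6pc serves glucose output and was picked after its values were seen, had -0.048 ± 0.10. It had -0.12 with the values as deposited, -0.10 with a common median, -0.016 without f/f replicate 1, -0.081 without d/d replicate 1 and -0.023 without d/d replicate 2. Genes of glycolysis and glycogen passed as higher as a list, with a mean of 0.19, though 8 of the 15 members were higher and 7 lower (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0181, and adjusted p = 0.211 with an estimated correlation). Ppp1r3b (0.91 ± 0.17), Ppp1r3c (0.87 ± 0.16) and Pygl (0.39 ± 0.12), which act on glycogen, passed when adjusted over the list alone, while 0 of the 15 passed over all genes in limma and 4 had an unadjusted p under 0.05. Ppp1r3c passed over all genes without f/f replicate 3 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0388), and with array weights so did Ppp1r3c (adjusted p = 0.00946) and Ppp1r3b (adjusted p = 0.0173). Genes of lipid droplets and lipolysis passed as lower as a list, with a mean of -0.32 and 11 of 15 lower (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000461, and adjusted p = 0.211 with an estimated correlation). Over all genes 0 of these passed and 5 had an unadjusted p under 0.05, and adjusted over the list alone G0s2 (-1.75 ± 0.32), Plin5 (-0.80 ± 0.14) and Plin2 (-0.60 ± 0.16) did. Plin5 and Plin2 passed over all genes without f/f replicate 3 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0415 and 0.0478). The lipoprotein list had a mean of 0.14 with 14 of 20 higher (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0255, and adjusted p = 0.211 with an estimated correlation), and Apoc2 (0.52 ± 0.10), the activator of Lpl, passed in it when adjusted over the list alone, while 0 passed over all genes in limma and 3 had an unadjusted p under 0.05. That list call ended with the values as deposited (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0665), with a common median (adjusted p = 0.0525) and without f/f replicate 1 or 2 (adjusted p = 0.0592 and 0.0665, and from 0.014 to 0.0665 over its alternatives). Among 12 targets of the oxysterol receptors LXR, Lpl rose and 11 did not pass, with a mean of 0.27 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0218, and adjusted p = 0.296 with an estimated correlation). That call ended without f/f replicate 1 or 3 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0609 and 0.131) or d/d replicate 2 (adjusted p = 0.056) and with array weights (adjusted p = 0.113), with 0.00628 to 0.131 over its alternatives. The median of the list was 0.045.

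Complement and coagulation genes passed as higher as a list, with 21 of 23 higher and a mean of 0.24 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.86e-09, and adjusted p = 0.193 with an estimated correlation). C1s1 (0.49 ± 0.10), Proc (0.44 ± 0.10) and Cfi (0.47 ± 0.12) were among 6 that passed when adjusted over the list alone, while 0 passed over all genes and 9 had an unadjusted p under 0.05. Interferon response genes passed as higher as a list, with 15 of 17 members positive and a mean of 0.23 (camera with Benjamini-Hochberg adjustment, adjusted p = 3.48e-05, and adjusted p = 0.211 with an estimated correlation). In limma 0 of the 17 passed over all genes, 5 had an unadjusted p under 0.05, and 5 passed as higher when adjusted over the list alone, among them Iigp1 (0.55 ± 0.098) and Igtp (0.63 ± 0.17). Heat shock genes passed as higher as a list, with 9 of 10 members positive and a mean of 0.31 (camera with Benjamini-Hochberg adjustment, adjusted p = 2.46e-05, and adjusted p = 0.173 with an estimated correlation). In limma 0 of the 10 passed over all genes, 4 had an unadjusted p under 0.05, and 4 passed as higher when adjusted over the list alone, among them Hsph1 (0.80 ± 0.11) and Dnaja1 (0.47 ± 0.10). Genes of the unfolded protein and integrated stress response, tested as 1 list, passed as higher, with 16 of 21 members positive and a mean of 0.16 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000868, and adjusted p = 0.211 with an estimated correlation). In limma 0 of the 21 passed over all genes, 6 had an unadjusted p under 0.05, and 5 passed as higher when adjusted over the list alone, among them Herpud1 (0.74 ± 0.14) and Hspa5 (0.44 ± 0.11). Averaged over all probe sets of a gene, Dnaja1 had 0.26, and Hsph1 passed over all genes (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0432). Without f/f replicate 3, Hsph1 passed over all genes, as did Oat and Gstm2 of the lists given next (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0269, 0.0112 and 0.0128). Genes of hepatocytes near the central vein passed as lower as a list, with 15 of 17 lower and a mean of -0.29 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.39e-06, and adjusted p = 0.173 with an estimated correlation). That list holds Cyp7a1 and Cyp27a1, and also Oat (-0.80 ± 0.14), Lect2 (-0.51 ± 0.13) and Gulo (-0.40 ± 0.099), all 5 past the threshold when adjusted over the list alone, while 0 of the 17 passed over all genes in limma and 6 had an unadjusted p under 0.05. NRF2 targets and glutathione enzymes had a mean of -0.24 with 14 of 19 lower, among them Gstm2 (-0.92 ± 0.21), and xenobiotic metabolism genes a mean of -0.15 with 12 of 15 lower (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0025 and 0.0443, and adjusted p = 0.423 and 0.284 with an estimated correlation). Of these lists 0 members passed over all genes in limma, 5 and 4 had an unadjusted p under 0.05, and adjusted over the list alone Gstm2 passed in the first and 0 in the second. The first call ended without f/f replicate 1 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0609). The second ended without f/f replicate 1 or 2 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.183 and 0.188) or d/d replicate 1 or 2 (adjusted p = 0.0542 and 0.0836). It also ended with no dim filter, where the mean was -0.043, with a pseudocount of 64, where it was -0.065, with a pseudocount of 1 (-0.16), with a common median (-0.15) and with the lowest 60% left out (-0.15). Over all alternatives the adjusted p ran from 3.02e-06 to 0.0609 for the first and from 0.00618 to 0.198 for the second (camera with Benjamini-Hochberg adjustment). Members given as examples for these lists were picked after their values were seen.

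Of the lists for other cell types, that of Kupffer cells passed as lower, with a mean of -0.22 and 13 of 15 members lower (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00126, and adjusted p = 0.334 with an estimated correlation). Its most abundant member, Cd5l, had -0.32 ± 0.20 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.783), 0 of the 15 passed over all genes and 4 had an unadjusted p under 0.05. Without f/f replicate 3 Cd5l had -0.16, and without f/f replicate 1 -0.51. Without d/d replicate 1 the mean of the list was -0.15. The means of the lists for endothelial cells, stellate cells, cholangiocytes, lymphocytes and neutrophils were 0.050, -0.080, 0.012, -0.045 and 0.025, where the median of the neutrophil list was -0.011. Those for erythroid cells, pancreatic acinar cells, adipocytes, muscle and hepatocytes themselves were 0.084, -0.032, -0.13, 0.029 and 0.0082. These 10 lists did not pass, with camera adjusted p from 0.121 for stellate cells to 0.904 for cholangiocytes with Benjamini-Hochberg adjustment. The stellate list passed without f/f replicate 3 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0279) or d/d replicate 3 (adjusted p = 0.0273) and with array weights (adjusted p = 0.0113). In those 3 settings it had adjusted p = 0.533, 0.428 and 0.409 with an estimated correlation (camera with Benjamini-Hochberg adjustment). The stellate mean was -0.13 without f/f replicate 3, -0.13 without d/d replicate 3 and -0.15 with array weights. It was -0.020 without f/f replicate 2 and -0.010 without d/d replicate 1. The erythroid mean was 0.033 without f/f replicate 3 and 0.039 without d/d replicate 3. In all, 14 of 37 lists passed with the preset correlation of camera, 7 in each direction, and 0 with an estimated correlation. With the directional test of fry, which asks whether members move one way on balance, the lipoprotein list and the fasting list passed (Benjamini-Hochberg adjusted p = 0.00824 and 0.0359).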

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

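The tests on control probe sets, RNA integrity, the fast and the clock, and the removal of f/f replicate 2 or 3 as a test of the cholesterol pattern, were chosen after the result was seen. Among probe sets outside the named genes, 3 without a gene name in the annotation differed between genotypes, all higher in d/d, out of 20 that passed of 27022 tested. Their log2 differences were 2.30 ± 0.18, 1.90 ± 0.15 and 1.37 ± 0.16 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00313, 0.00414 and 0.0367), and they are unnamed here.

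Chance was weighed for the genes past the threshold. The real split of the 6 arrays called 13 genes in limma and the highest of the other splits 0, so 1 of the 10 splits called as many, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, the other splits had 123 to 1742 genes and the real one 1076; the split with 1742 set f/f replicate 3, d/d replicate 1 and d/d replicate 2 against the rest. The strain is a mixed background, so a difference in the chromosome region around Errfi1 could travel with the genotype, but only if the groups inherited that region differently. If d/d was made from the f/f allele, both carry the same region and the comparison of neighbours has nothing to find. Of the 40 tested neighbours of Errfi1, 12.5% had an unadjusted p under 0.05 against 7.82% of other genes (two-sided Fisher's exact p = 0.239). In limma 0 of the 40 passed (5 at an unadjusted p under 0.05), so the called genes besides Errfi1 lie outside this set. A wider region, or an effect on distant genes, stays open. A different collection time of the groups stays open for the called genes and for Cyp7a1, and it was not tested on them. The clock score defined below differed by 0.82 (d/d minus f/f), with every d/d array above every f/f array. The deletion itself, the difference that the design names, stays open as well, as the design does not separate it from the time of collection.

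The array of f/f replicate 3 lay apart from the other 5 on the first principal component. Degraded RNA is argued against by the Actb difference of 1.18 on this array, under the highest of the other arrays at 1.37, and the same held for Gapdh. All 21 probe sets for 18S ribosomal RNA and added controls, 100%, were highest on this array, which is consistent with less labelled messenger RNA and more ribosomal RNA in this hybridization. Cells of another type stay open: lymphocyte markers had a median of 0.52 above the other f/f arrays, with a standard error of 0.16, where the bound, the interquartile range over all genes, was also 0.52, and the spread was taken into account after that value was seen. Lymphocyte markers were not alone: the medians were 0.36 for acinar cells, 0.32 for neutrophils and 0.20 for muscle. The remaining lists of other cell types had medians from -0.40 for endothelial cells to -0.011 for cholangiocytes. Beyond such cells, no biological explanation was tested.

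Cholesterol synthesis genes had a mean of -0.57 in d/d minus f/f, with a call at the preset correlation only (camera with Benjamini-Hochberg adjustment, adjusted p = 1.86e-09, and adjusted p = 0.334 with an estimated correlation of 0.62). Without f/f replicate 3 or f/f replicate 2 the means were -0.74 and -0.34, so neither array alone made the whole mean. The list passed in these fits at the preset correlation only (camera with Benjamini-Hochberg adjustment, adjusted p = 1.07e-14 and 0.000264, and adjusted p = 0.382 and 0.443 with an estimated correlation). These tests therefore do not tell the remaining difference from the spread between arrays. A longer fast in d/d would raise Igfbp1 and G6pc, which had differences of -2.13 and -1.25, the other direction. Both were known as falls when they were chosen, and the genotype may lower them itself and hide a longer fast. The fast therefore stays open. A different collection time stays open: the clock score, genes that peak with Dbp minus genes that peak against it, was 0.97 ± 0.12 in d/d and 0.15 ± 0.29 in f/f (SD, n = 3 each), a difference of 0.82 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give), with 8 of 10 genes of the first kind higher and 4 of 4 of the second lower. Within f/f the order ran the other way, with scores of -0.089, 0.079 and 0.47 beside list means of 8.58, 8.80 and 9.38 log2 for f/f replicates 3, 1 and 2, and 3 arrays are too few to decide. The genotype stays open, as the design does not separate it from the time of collection, and so does a part of the difference carried by f/f replicate 2.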

How the results depend on the processing

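The RNA integrity alternatives were chosen after seeing the data. The fall of Errfi1 kept its direction and stayed past the threshold under its 16 alternatives, between -6.40 and -5.43. The 6 rises and 7 falls became 10 rises with the mean of probe sets, 12 rises over all probe sets, 4 rises with a pseudocount of 1, where Abcd2 and Hgfac lost their calls, 11 and 12 with trend and robust eBayes, 124 and 90 with array weights, which gave f/f replicate 3 a weight of 0.178, and 136 and 73 at an unadjusted p under 0.05 and at least 1.5-fold; the cause was not tested. Leaving out 1 array gave 1 to 38 rises and 3 to 44 falls. With the replicate block, 0 genes rose and 1 fell, at 723 genes with an unadjusted p under 0.05 in limma, and 18 secondary lists passed where 13 did without it. Deviations of same-numbered arrays from their group means had correlations across genes of -0.0032, -0.14 and -0.47. Those of differently numbered arrays ran from -0.47 to 0.43. Same-numbered arrays thus showed no shared deviation, but 3 arrays per group are too few to exclude that the numbers pair the samples. The mean of cholesterol synthesis was -0.34 to -0.74 without 1 array, and its call ended with an estimated correlation, at a mean of -0.57. Between 10 and 18 secondary lists passed over the alternatives at the preset correlation of camera, and 0 with an estimated correlation. Of 42 list members picked as examples after their values were seen, 31 passed over all genes with array weights. With trend and robust eBayes 4 did, and without f/f replicate 3 13 did. All genes together gave 214, 23 and 82 calls in these settings, where the main fit gave 13. The choice of the examples favours such passes, so these counts are no separate support for the lists. Of 1714 gene and list values under alternatives, 44 turned their sign, none of them past the threshold in both settings. Signal over background limits the differences of dim genes, which the pseudocount draws toward 0.

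With array weights the turned values were 0.00302 for sterol transport, -0.0169 for Abcg8, 0.15 for Egfr, 0.00615 for the cell cycle, -0.0114 for EGF receptor genes, -0.0235 for endothelial cells, 0.0614 for lymphocytes, -0.0118 for nuclear receptors and 0.0457 for acinar cells. With a stricter dim filter they were 0.0271 for adipocytes, 0.0139 for lymphocytes, -0.0621 for muscle and -0.0355 for neutrophils, and with no filter 0.00274 for sterol transport. As deposited they were -0.00237 for Slc10a1, -0.00375 for cholangiocytes and -0.00429 for hepatocytes, and with a common median 0.000419 for sterol transport. With the mean of probe sets they were 0.0209 for fatty acid synthesis and 0.0244 for ketone body synthesis.

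Leaving out 1 array gave -0.0252 to 0.0186 for sterol transport, -0.0516 to 0.0238 for Abcb11, -0.0265 to 0.0361 for Abcg8, -0.21 to 0.15 for Egfr and -0.0376 to 0.0586 for the Actb integrity difference. For lists it gave -0.00093 to 0.12 for EGF receptor genes, -0.10 to 0.00789 for the cell cycle, -0.0316 to 0.0476 for cholangiocytes, -0.0762 to 0.0205 for fatty acid synthesis, -0.00738 to 0.0284 for hepatocytes and -0.16 to 0.0777 for ketone body synthesis. It gave -0.0391 to 0.10 for endothelial cells, -0.0994 to 0.0612 for lymphocytes, -0.0205 to 0.0936 for muscle, -0.0455 to 0.14 for neutrophils, -0.0144 to 0.0814 for nuclear receptors and -0.0832 to 0.053 for acinar cells.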

Other observations

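The members named as examples here were picked after their values were seen, while the test on FOXO1 was chosen before its result was seen. Clock genes had differences of both signs. Dbp (1.74 ± 0.53), Per2 (0.45 ± 0.14) and Hlf (0.54 ± 0.17) had positive log2 differences and Arntl (-0.53 ± 0.11) and Nfil3 (-0.74 ± 0.12) negative ones (SE, n = 3 per group). Of 17 members, 4 passed as higher and 2 as lower when adjusted over the list alone, while 0 passed over all genes in limma and 7 had an unadjusted p under 0.05. The mean of the list was 0.21 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0949), and it passed without f/f replicate 2 (mean 0.34, adjusted p = 0.00304) or d/d replicate 1 (mean 0.24, adjusted p = 0.0358). These fits had adjusted p = 0.387 and 0.541 with an estimated correlation, and all arrays adjusted p = 0.594 (camera with Benjamini-Hochberg adjustment). Without f/f replicate 3 its mean was 0.099 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.33), Dbp had 1.06 and Hlf 0.36. Genes of hepatocytes near the portal vein also split: Aldh1b1 (1.34 ± 0.28) and Hsd17b13 (0.62 ± 0.13) were positive, Etnppl (-1.12 ± 0.25) and Asl (-0.54 ± 0.097) negative, and adjusted over the list alone 5 of 18 passed as higher and 2 as lower, with 0 past the threshold over all genes and 8 at an unadjusted p under 0.05. That list had a mean of 0.19 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0938) and passed without f/f replicate 2 (adjusted p = 0.0489, and adjusted p = 0.443 with an estimated correlation). Averaged over all probe sets of a gene, Hsd17b13 had 0.27, Etnppl -0.68 and Arntl -0.30, and Per2 had 0.29 with a pseudocount of 64. Without 1 array, some passed over all genes: Nfil3 and Etnppl without f/f replicate 3 and Aldh1b1 without f/f replicate 2 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0415, 0.0388 and 0.0422).

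Acute phase genes varied within both groups. Saa1 had log2 means of 13.50 ± 1.27 in f/f and 11.60 ± 1.67 in d/d (SD, n = 3 each), a difference of -1.91 ± 0.85 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.65), and the list a mean of -0.40 and a median of -0.043 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.451). The list passed without f/f replicate 1 (mean -0.69, camera with Benjamini-Hochberg adjustment, adjusted p = 0.00247) or d/d replicate 2 (mean -0.61, adjusted p = 0.0235). With an estimated correlation these fits had adjusted p = 0.69 and 0.717, and all arrays adjusted p = 0.893 (camera with Benjamini-Hochberg adjustment). Its mean was -0.10 without f/f replicate 2 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.5) and -0.22 without d/d replicate 1 (adjusted p = 0.906), where Saa1 had -1.11. Targets of PPARalpha and fatty acid oxidation had a mean of -0.17 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0553), which passed without f/f replicate 2 or 3 (means -0.27 and -0.22, adjusted p = 0.00646 and 0.0081) or d/d replicate 1 (mean -0.29, adjusted p = 0.00132). With an estimated correlation these 3 fits had adjusted p = 0.686, 0.663 and 0.558, and all arrays adjusted p = 0.787 (camera with Benjamini-Hochberg adjustment). It also passed with the values as deposited (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0296), with no dim filter (adjusted p = 0.023), with array weights (adjusted p = 0.0327) and with a pseudocount of 64 (adjusted p = 0.0373, and adjusted p from 0.683 to 0.777 with an estimated correlation). The mean was -0.028 without f/f replicate 1 and -0.092 without d/d replicate 2 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.973 and 0.272). Male-predominant and female-predominant genes had means of -0.15 and -0.29 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.243 and 0.126), the first past the threshold without f/f replicate 2 (adjusted p = 0.00751) and the second without d/d replicate 1 (adjusted p = 0.0337). With an estimated correlation these had adjusted p = 0.443 and 0.304 (camera with Benjamini-Hochberg adjustment). The male-predominant mean was -0.27 without f/f replicate 2, -0.037 without f/f replicate 3 and -0.093 without d/d replicate 2. The female-predominant mean was -0.062 with no dim filter and -0.14 with a pseudocount of 64. Averaged over all probe sets of a gene, the female-predominant list passed (camera with Benjamini-Hochberg adjustment, adjusted p = 0.017, and adjusted p = 0.213 with an estimated correlation). With the replicate number as a block, the lists for PPARalpha, acute phase, the clock, female-predominant and periportal genes passed (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0105, 0.0105, 0.0334, 0.0279 and 0.0171). With that block they had adjusted p = 0.333, 0.525, 0.548, 0.333 and 0.333 with an estimated correlation (camera with Benjamini-Hochberg adjustment), and whether the numbers pair the samples is not known. The lists of fatty acid synthesis, ketone body synthesis and the cell cycle had means of -0.029, -0.045 and -0.063 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.773, 0.775 and 0.594).

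Igfbp1 and G6pc are targets of the transcription factor FOXO1, and lower FOXO1 activity in d/d was tested as a hypothesis on 12 other targets listed before their values were looked at. Their mean was -0.043, with 8 of 12 lower and 0 past the threshold in limma (camera p = 0.517, p = 0.694 with an estimated correlation), which decides neither way. The 3 at an unadjusted p under 0.05 lay on both sides, Klf15 (0.43 ± 0.12) and Insr (0.32 ± 0.11) higher, against the hypothesis, and Ccng2 (-0.31 ± 0.13) lower.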
